A study of Mus musculus with 8 samples.

How the data were processed

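Binding of the transcription factors E2f3 and Myc was measured in mouse intestine by ChIP-exo-seq, chromatin immunoprecipitation in which an exonuclease trims the precipitated DNA up to the crosslinked protein. Per the labels, crypt cells and villus cells came from control mice and from mice in which Rb was deleted by an inducible intestinal Cre recombinase (Ah-cre). The antibodies against E2f3 and against Myc came from Santa Cruz, per the labels. Every combination of cell type, genotype and antibody was represented by 1 library, which gave 8 libraries in 8 groups. No input or control-antibody library was used here.

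Per the submitters' processing notes, Bowtie2 2.2.1 and MACS2 2.0.10 were used and positions refer to the mouse build mm9. Per the names of the deposited files, the lists hold binding events called by GEM that overlap MACS2 peaks, from merged data with duplicate reads kept. What was merged, the version and settings of GEM, the thresholds and the numbers of reads are not given in the sources used here. Each deposited list gives 1-bp positions with a score between 2 and an upper cap. What the authors' score measures is not stated, and neither is any normalization between lists, so it was used to rank the sites within a list, to match genes on score within a library and to choose the genes to name. Scores of different libraries are printed as deposited, and their differences were not interpreted. Sequencing depth is unknown for every library. Because a deeper library yields a longer list, differences between lists were also computed at equal list length.

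With the deposited positions, the centre of the nearest E2F motif lay at a median of 1 bp downstream on both strands in the 4 E2f3 libraries. The positions were therefore taken to count from 0, and all coordinates given here are the deposited positions plus 1. Of E2f3 sites with an E2F motif within 50 bp, between 72.3% and 84.3% per library and strand lay exactly at the motif's centre. The centre of an E-box falls between adjacent bases, so a site at either of them was counted as lying at the centre. This held for 88.7% of Rb-deficient crypt Myc sites with an E-box within 50 bp, and for 2.72% of control crypt Myc sites with an E-box. Shares of sites with a motif are therefore not independent of how the events were placed, and a wider window was added as an alternative.

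Genes and sequence were taken from the reference assembly NCBIM37, on which mm9 rests, and from the GENCODE M1 annotation. Of the sites, between 145 and 201 per library lay on contigs outside that reference. These stayed in the counts of sites and overlaps but received no gene or motif. A promoter site was a site within 1 kb of a start site of a protein-coding gene, over 45974 start sites of 22232 genes. A gene counted as bound when it had at least 1 promoter site, so a site between divergent genes counted for both. The share of promoter sites was compared with the mean over 100 circular shifts of each list within its chromosomes, and the number of bound genes with the mean over 20 such shifts.

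Sites of different lists were called shared when they lay within 250 bp of each other, regardless of strand. Sharing was given as a share of each list and as a fold over the mean of 100 circular shifts on the reference chromosomes. Motif shares were the shares of sites with the E2F motif TTSSCGC (S is C or G) on either strand, or the E-box CACGTG, within 50 bp. They were set against windows 2 kb to each side of the same sites. The cell cycle homology region (CHR) element TTYGAA (Y is C or T) was counted in the same way after the first results were known. Intervals are exact 95% binomial (Clopper-Pearson) intervals. They cover counting error only and say nothing on the variation between mice. With 1 library per group, no group was tested against another and no p-value is given.

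The 20 gene lists were written before the data were examined. They were DNA replication, nucleotide synthesis for S phase, Rb-E2F and G1/S regulators, G2/M and mitosis, DNA repair and checkpoint, ribosome biogenesis, the Myc network, metabolic and translation targets of Myc, apoptosis and the p53 pathway, intestinal stem cell and crypt, villus enterocyte, intestinal transcription factors, secretory lineages, immune cells, stroma and endothelium, genes of other tissues, housekeeping, replication-dependent histones, ribosomal proteins and olfactory receptors. All members but 1, of the secretory list, were found in the annotation. For each list and library the number of bound members was given with its percentile among 10000 random lists of the same size drawn from all protein-coding genes. For the difference between a pair of libraries, the random lists were drawn from genes bound in either library. For the villus E2f3 pair, a further 10000 random lists were matched on the site score in 20 score classes. These percentiles describe the libraries and are not tests of the genotypes.

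The rule for named genes was fixed at the same time. Rb1, E2f1, E2f2, E2f3 and Myc were named in every case. From each list and pair, up to 4 bound members with the highest score and up to 2 unbound members in alphabetical order could be named. For each pair and direction, the 5 genes with the highest-scored promoter site and no site within 5 kb of a start site in the other library were named. The text gives those members that the account of a list needs. Genes named outside the rule are marked as such. Results for some genes that the rule would name are not reported here.

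The comparisons were Rb-deficient against control, villus against crypt, and Myc against E2f3, each with the other factors held fixed, which gave 12 pairs. The alternatives set in advance were other sharing distances (100 and 1000 bp), the upper part of each list by score, equal list lengths, events within 500 bp merged, autosomes and X only, promoter windows of 500 bp and 5 kb, random lists from bound genes only, and motif windows of 25 and 100 bp. Chosen after seeing the data were the restriction to sites with no site of the other antibody within 250 bp in any of its 4 libraries, the restriction of the antibody comparison to promoter sites, and the motif window of 250 bp.

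The overlap count was tested on simulated positions made from the Rb-deficient villus E2f3 list, of which 14667 sites on the autosomes and X were used. With 2000 and 8000 planted shared sites, 2101 and 8192 were found, beside means of 41.1 and 65.3 after shifting. The gene assignment was checked by a separate slower count for 394 genes, and 394 matched. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.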

Results

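Binding sites of E2f3 and Myc were mapped by ChIP-exo-seq in crypt and villus cells of control and Rb-deficient mouse intestine. Crypts hold the dividing stem and progenitor cells and villi the differentiated cells. Rb, encoded by Rb1, is the pocket protein that restrains E2F transcription factors. Per the series description, binding was examined in normal and Rb-deficient cells. The 4 E2f3 libraries held 32666 sites in control crypt, 27396 in Rb-deficient crypt, 7405 in control villus and 14843 in Rb-deficient villus. The 4 Myc libraries held 159181 sites in control crypt, 31397 in Rb-deficient crypt, 7223 in control villus and 4119 in Rb-deficient villus. Each group had 1 library and the sequencing depth is unknown. No difference below therefore has a replicate check, and intervals cover counting error only. Site lists do not measure the deletion of Rb1, so the genotype labels could not be checked.

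E2f3 sites lay at promoters more often than shifted positions and had the E2F motif more often than their flanks. Most E2f3 sites still lay outside promoters and had no such motif within 50 bp. A clear excess of the E-box, the sequence bound by Myc with its partner Max, was seen in the Rb-deficient crypt Myc library. Promoter sites made up 10.5% of E2f3 sites in control crypt, 18.5% in Rb-deficient crypt, 13.5% in control villus and 19.6% in Rb-deficient villus. Randomly shifted positions gave 2.27% to 2.32%. For Myc the promoter shares were 2.70% in control crypt, 5.93% in Rb-deficient crypt, 2.38% in control villus (interval 2.03% to 2.76%) and 2.85% in Rb-deficient villus (2.35% to 3.42%). The shifted values were 2.24% to 2.30%.

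The E2F motif lay within 50 bp of 6.57% of E2f3 sites in control crypt, 9.30% in Rb-deficient crypt, 11.3% in control villus and 11.0% in Rb-deficient villus. Windows 2 kb away gave 0.528% to 0.583%. Among E2f3 promoter sites the shares were 39.1%, 32.7%, 58.2% and 37.7% in the same order. The E-box lay within 50 bp of 6.31% of Rb-deficient crypt Myc sites (6.05% to 6.59%), against 1.08% in the flanks, and of 31.1% of its promoter sites. In control crypt Myc the share was 1.43% (1.38% to 1.49%) against 1.06%, a small excess, and 4.08% of promoter sites. Control crypt E2f3 sites had an E-box in 1.53% (1.40% to 1.67%) against 1.08%, so an excess of this size was not particular to the Myc antibody. Control villus Myc had 1.17% (0.930% to 1.45%) against 1.04%, and Rb-deficient villus Myc 1.65% (1.28% to 2.10%) against 1.01%. Many events lay exactly on the motif, which ties these shares to the calling. Within 250 bp, where exact placement matters less, the E2F shares were 3.53, 4.79, 5.18 and 5.62 times those of the flanks in the 4 E2f3 libraries. The E-box shares were 1.40, 2.33, 1.48 and 1.54 times those of the flanks in the 4 Myc libraries. At control crypt E2f3 sites the E-box ratio within 250 bp was 1.47, so only the 2.33 of Rb-deficient crypt Myc lay clearly above it.

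**Figure D1:**
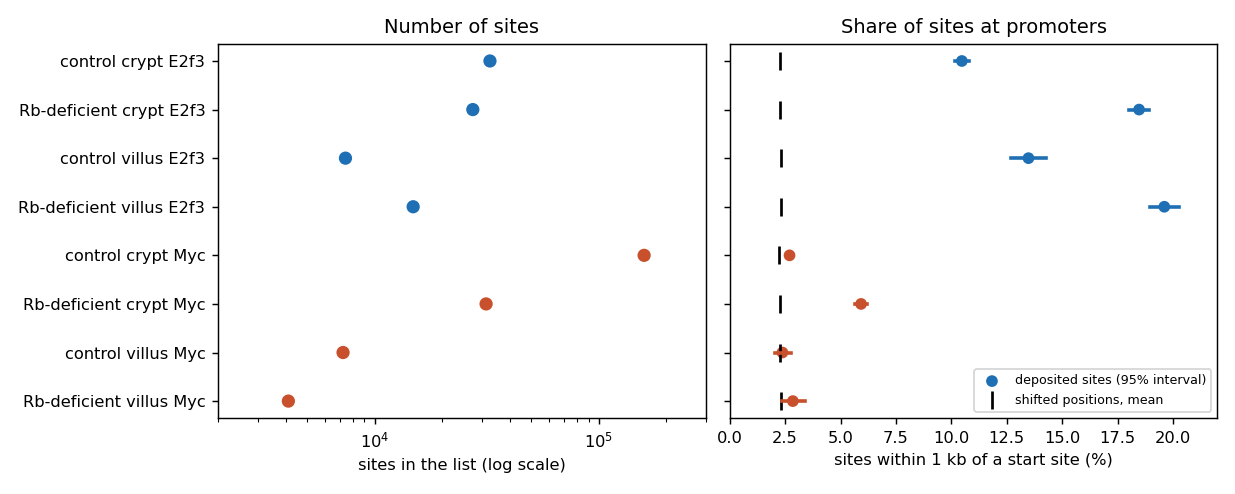
Number of sites per library (left, log scale) and share of sites within 1 kb of a start site in percent (right; points with 95% intervals, black ticks for shifted positions), with E2f3 libraries in blue and Myc libraries in red. E2f3 promoter shares run from 10.5% to 19.6%, and the villus Myc shares of 2.38% and 2.85% lie near the shifted values.

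**Figure D2:**
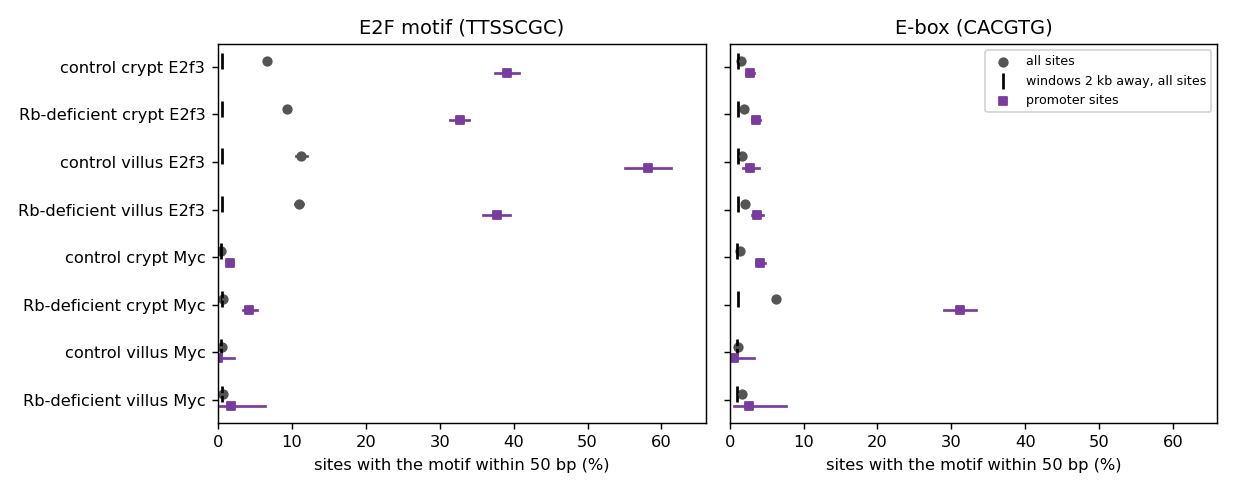
Share of sites in percent with the E2F motif (left) and the E-box (right) within 50 bp, for all sites (grey points), promoter sites (purple squares) and windows 2 kb away (black ticks), with 95% intervals. The E-box share at promoter sites reaches 31.1% in Rb-deficient crypt Myc and 4.08% in control crypt Myc.

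In control villus, E2f3 was found at genes of DNA replication but at hardly any gene of mitosis, whereas in Rb-deficient villus it was found at both. Of 38 replication genes, 24 had an E2f3 promoter site in control villus and 33 in Rb-deficient villus. Of 29 genes of G2/M and mitosis, 1 had a site in control villus and 22 in Rb-deficient villus. A count of 1 is ordinary for a random list of this size in control villus (median 1, percentile 44.4), and among genes bound in at least 1 library it lay at percentile 6.99 (median 3), so the mitotic list did not stand apart there, whereas the replication list did (percentile 100 in both). That 1 gene was Cdk1, the kinase that drives entry into mitosis, which is named here after its values were seen. The number of genes with an E2f3 promoter site was 994 in control villus and 2760 in Rb-deficient villus, beside 166 and 327 after random shifts. Of these genes 832 were common, 1928 had a site in Rb-deficient villus only and 162 in control villus only.

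Mitotic genes were among those with the highest-scored sites present only in Rb-deficient villus. The 5 genes were Cdca3 (score 304.89), a trigger of mitotic entry, its neighbour Usp5 (304.89, the same site), Incenp (246.38), Top2a (183.59) and Aurkb (178.17). Incenp and Aurkb encode subunits of the chromosomal passenger complex and Top2a encodes topoisomerase II. The Cdca3 site lay on chromosome 6 at 124780222, 13 bp upstream of a start site and 720 bp upstream of the start of Usp5. The Aurkb site lay on chromosome 11 at 68859145, 4 bp upstream of the start. Nuf2, a kinetochore gene, had a site with a score of 147.8 on chromosome 1 at 171461527, in the 5' UTR. Aurka and Cdc20 had no promoter site in any E2f3 library; Cdc20 is named after its values were seen. The 5 highest-scored genes present only in control villus were Pds5b (115.26), a cohesin regulator, Trpc2 (95.42), Itfg2 (67.36), Athl1 (63.76) and Utp20 (58.48).

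Replication genes had high-scored sites in both villus libraries. Mcm3, a subunit of the replicative helicase, scored 163.21 in Rb-deficient and 169.81 in control villus. Prim1, the primase catalytic subunit, scored 144.59 and 161.21. Mcm4 scored 142.17 and 89.59, and Cdc6, which loads the helicase, 139.64 and 44.43. Rfc5 had no promoter site in either villus library. Among 10 genes of nucleotide synthesis, 5 had a site in control villus and 10 in Rb-deficient villus. The site at Tyms, the thymidylate synthase gene, scored 15.65 in control and 188.24 in Rb-deficient villus, and Rrm2, of ribonucleotide reductase, had a site (86.62) in Rb-deficient villus only. Of 28 Rb-E2F and G1/S regulators, 10 and 19 had a site. E2f3 itself scored 29.55 and 232.38 and E2f8 17.24 and 127.47. E2f2 had a site in both villus libraries (67.68 and 46.78), E2f1 in neither, and Rb1 low-scored sites in both (3.47 and 5.64). No scale of the scores between libraries is stated, so scores of different libraries are given as deposited, here and below, and their differences are not interpreted.

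The share of best sites with the strict E2F motif differed between the replication and the mitotic list, although single sequences were alike across the lists. At Prim1, on chromosome 10 from 127452239 to 127452279 around the site in the 5' UTR, the 41 bp were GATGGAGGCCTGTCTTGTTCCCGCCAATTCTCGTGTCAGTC, with the E2F motif TTCCCGC at the centre. At Mcm3, on chromosome 1 from 20810351 to 20810391, 12 bp upstream of the start, they were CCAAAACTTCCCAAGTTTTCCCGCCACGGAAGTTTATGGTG. At Aurkb, on chromosome 11 from 68859125 to 68859165, they were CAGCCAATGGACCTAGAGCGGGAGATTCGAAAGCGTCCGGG, and at Top2a, from 98885521 to 98885561 on chromosome 11, 38 bp upstream of the start, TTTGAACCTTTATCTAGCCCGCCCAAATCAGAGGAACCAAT. Neither Aurkb nor Top2a had TTSSCGC within 50 bp. Both sequences hold its SSCGC part at the site, as CCCGC at Top2a and, on the other strand, as GCGGG at Aurkb. The replication gene Cdc6 likewise had GCGGG at its site, at 98769127 on chromosome 11. Its nearest strict match, TTGGCGC, lay away from the site, from 98769156 to 98769162. Such partial matches were not counted, so the shares that follow cover the strict motif only. Over the lists, 28 of 33 best replication sites in Rb-deficient villus had the E2F motif, 84.8% (68.1% to 94.9%), against 4 of 22 mitotic sites, 18.2% (5.19% to 40.3%).

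Most other lists also had more members bound in Rb-deficient than in control villus, as did all genes together (2760 against 994). DNA repair and checkpoint genes went from 11 to 17 of 20, with Atad2 (67.48 in control, 266.2 in Rb-deficient), Bard1 (18.88 and 125.61) and Chek1 (12.33 and 97.56) in both and Fanci (119.96) in Rb-deficient villus only. Replication-dependent histone genes went from 14 to 21 of 69, ribosomal protein genes from 6 to 20 of 83, with Rps20 (68.47 and 101.86) in both, and housekeeping genes from 3 to 7 of 20. Ribosome biogenesis genes had 7 and 8 of 26, with Nop58 (78.91 and 219.94). Metabolic and translation targets of Myc had 6 and 11 of 23, the Myc network 1 and 4 of 11, and apoptosis and p53 genes 4 and 7 of 13. Myc and Mycn had an E2f3 site in Rb-deficient villus (18.58 and 54.69) and none in control villus.

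Set against all genes bound in either villus library, the mitotic list stood apart in 1 direction and several lists, replication among them, in the other. Of 22 mitotic genes bound in either library, 21 were bound in Rb-deficient villus only, where random lists had a median of 15, and this lay at percentile 99.9. Of 35 replication genes 11 were, against a random median of 23 and a percentile of 0.00. Low percentiles were also found for histones (8 of 22, percentile 0.24), ribosome biogenesis (2 of 9, percentile 0.47) and DNA repair (7 of 18, percentile 1.1). With 7405 sites in each list, 19 of 20 mitotic genes (random median 9, percentile 100) and 9 of 33 replication genes (random median 15) were bound in Rb-deficient villus only. Lists matched on score had a median of 9 genes without a control site and a maximum of 17, against the 21 mitotic genes. Matched in the same way, the 11 replication genes (matched median 14, percentile 12.9), 8 histone genes (median 8) and 7 repair genes (median 7) no longer stood apart, while the 2 ribosome biogenesis genes (median 5, percentile 1.01) and 5 metabolic and translation targets of Myc (median 8, percentile 1.76; 9.10 before matching) were low. At equal length the promoter genes numbered 1569 and 994.

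Of the Rb-deficient villus E2f3 sites, 5626 or 37.9% (37.1% to 38.7%) lay within 250 bp of a control villus site, 273 times the shifted mean. In reverse, 74.1% of control villus sites had a Rb-deficient partner, and at equal list length 58.0% of Rb-deficient sites did. Promoter sites that both villus libraries shared had the E2F motif in 59.0% of 830 cases (55.6% to 62.4%). Those in Rb-deficient villus without a control site had it in 29.0% of 2046 (27.1% to 31.1%).

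**Figure D3:**
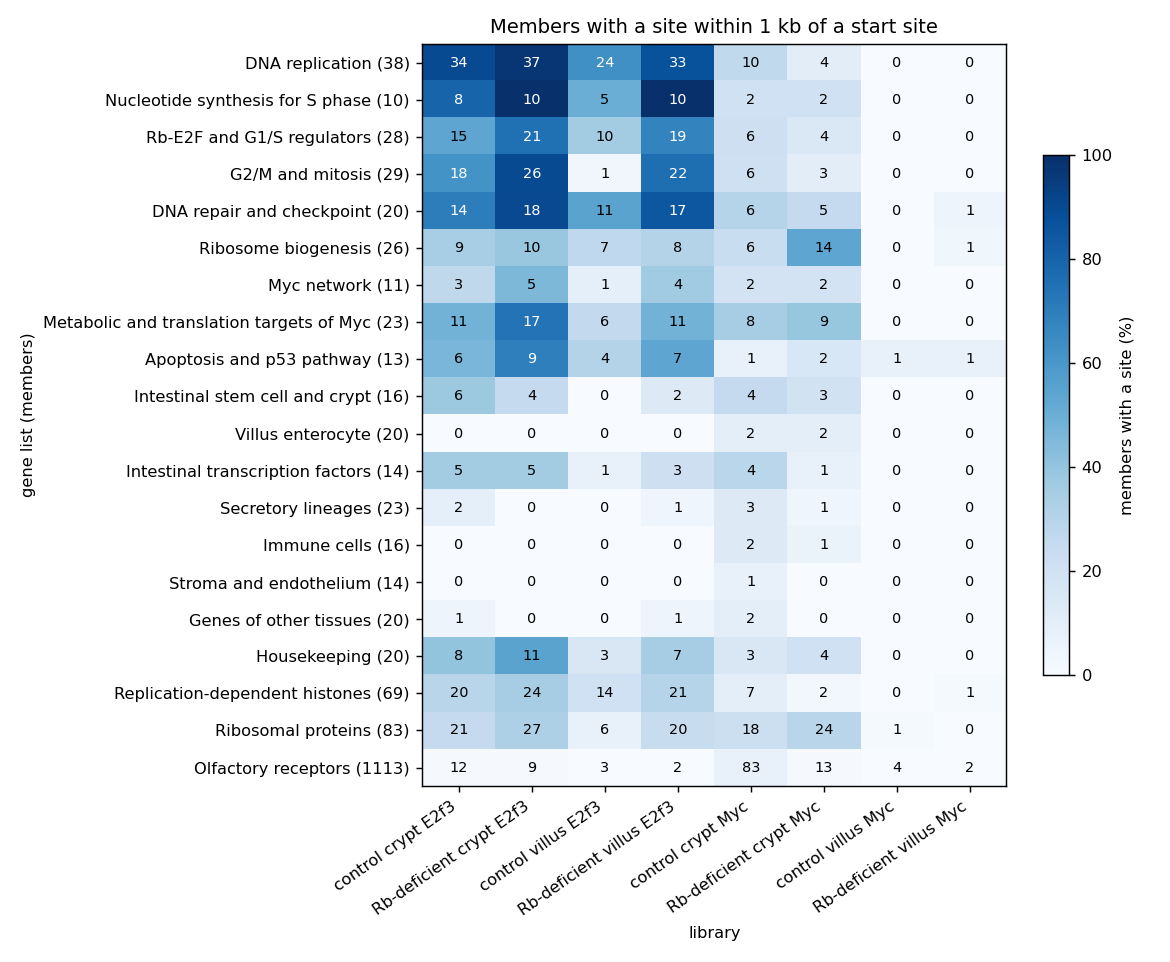
Number of members of each fixed gene list (vertical axis, members in brackets) with a site within 1 kb of a start site in each of the 8 libraries (horizontal axis), coloured by the percentage of members. The mitotic list has 1 of 29 members in control villus E2f3 and 22 in Rb-deficient villus E2f3, and ribosome biogenesis has 14 of 26 in Rb-deficient crypt Myc.

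In crypts, E2f3 was found at replication and mitotic genes in both genotypes. Replication genes had 34 of 38 members bound in control crypt and 37 in Rb-deficient crypt, mitotic genes 18 and 26 of 29, nucleotide synthesis genes 8 and 10 of 10, Rb-E2F and G1/S regulators 15 and 21 of 28, and repair and checkpoint genes 14 and 18 of 20. Of the 27 mitotic genes bound in either crypt library, 9 were bound in Rb-deficient crypt only, against a random median of 10. With 4119 sites from each list, 11 mitotic genes were bound in control crypt and 19 in Rb-deficient crypt. Incenp scored 227.51 in control crypt and had a score at the cap in Rb-deficient crypt, as did Bub1 (110.39 in control crypt), which encodes a spindle checkpoint kinase. Mcm3, Prim1, Mcm4, Tyms, Atad2 and Aurkb reached the cap in both. E2f1 had a promoter site in both crypt libraries (44.97 and 53.27), E2f2 (206.15 and 187.56) and Myc (121.39 and 127.61) as well. Rb1 had a site in Rb-deficient crypt (44.2) and none in control crypt.

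The crypt E2f3 lists bound 3240 genes in control and 4493 in Rb-deficient mice, with 2663 in both, 1830 in Rb-deficient only and 577 in control only. The highest-scored genes of Rb-deficient crypt only included Zfp367 (180.55), Tra2b (162.53), a splicing factor gene, Dyrk1a (112.2) and Anapc7 (112.02), a subunit of the anaphase-promoting complex. Those of control crypt only were Fuca1 (66.1), Zmat1 (51.37), 1110049F12Rik, Il1rl1 (44.78) and Rbm4b (36.33). Ribosome biogenesis genes had 9 and 10 members bound in control and Rb-deficient crypt, metabolic targets of Myc 11 and 17, the Myc network 3 and 5, apoptosis genes 6 and 9, housekeeping genes 8 and 11, histones 20 and 24, and ribosomal proteins 21 and 27. Of the Rb-deficient sites 69.5% were shared with control crypt, and of the control sites 58.2% with Rb-deficient crypt. At equal length 65.4% of Rb-deficient sites were shared.

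Compared with crypts of the same genotype, control villi lacked E2f3 at mitotic genes while Rb-deficient villi did not. In control mice, 17 of the 18 mitotic genes with a crypt site had none in villus, whereas 24 of 34 replication genes had a site in both. Over all genes, 2342 of the 3240 with a crypt site had none in villus. The highest-scored genes bound in control crypt only were Aurkb, Tcfap4 (277.04), Iqgap3 (265.88), H2afx (262.19), a histone variant gene, and Top2a (259.14). With 7405 sites from each list, 12 of 13 mitotic genes were bound in crypt only. In Rb-deficient mice, 21 of 27 mitotic genes and 33 of 37 replication genes were bound in both crypt and villus, as were 2385 of all 4868 genes bound in either. The highest-scored genes of Rb-deficient crypt only were Pds5b, Trpc2 (210.24), Syngr4 and Tmem143 (183.81, the same site) and D6Wsu163e (138.77).

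Control villus E2f3 sites lay mostly among crypt sites, with 6664 of 7405 shared (89.3% to 90.7%), and 78.9% (78.3% to 79.6%) of Rb-deficient villus sites were shared with Rb-deficient crypt. At equal length the shares were 60.2% and 63.6%. Of control villus genes 898 were bound in crypt too and 96 were not, among them Tra2b (37.48), 4931408C20Rik, Sh3bp4 (24.85) and Arl6ip6 (21.22). Of Rb-deficient villus genes 2385 were bound in crypt too and 375 were not, among them Ank1 (48.81), Xkr9 (31.29), Cenpl (21.57), a centromere protein gene, Zmat1 (21.29) and Csnk1g2 (21.13). Of the 1928 genes bound in Rb-deficient but not control villus, 1110 or 57.6% were bound in control crypt, 1579 or 81.9% in Rb-deficient crypt and 264 in neither. When E2f3 sites of the 4 libraries were joined into 42322 regions, 4939 held sites of all 4, 4991 of both crypts and Rb-deficient villus, 1124 of both crypts and control villus, and 1249 of Rb-deficient crypt and villus alone.

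In Rb-deficient crypts, Myc was found at genes that make ribosomes. Of 26 ribosome biogenesis genes, 14 had a Myc promoter site in Rb-deficient crypt (percentile 100) and 6 in control crypt (percentile 78.2). Against random lists of genes bound in at least 1 library, the percentiles were 100 and 9.42. Ribosomal protein genes had 24 and 18 of 83, and metabolic and translation targets of Myc 9 and 8 of 23. Within 5 kb of a start site, where the control crypt list had 11795 genes and the Rb-deficient one 4484, control crypt had more of both (53 against 33 ribosomal protein genes and 17 against 12 metabolic targets), and ribosome biogenesis had 14 in Rb-deficient and 11 in control crypt. Of the 16 ribosome biogenesis genes bound in either crypt library, 10 were bound in Rb-deficient crypt only, against a random median of 3 and at percentile 100, and of 29 ribosomal protein genes 11 were (random median 5). Only 6 of the 10 and 3 of the 11 had no control crypt site within 5 kb. These counts run against list length, as the control crypt list was the longer, but that list had little E-box excess (1.43% against 1.06%). With 31397 sites from each list, 12 of 14 ribosome biogenesis genes and 22 of 24 ribosomal protein genes were bound in Rb-deficient crypt only, but so were 60.5% of all genes bound in either. The random medians were 8 and 15, and ribosome biogenesis (percentile 97.4) then lay just within the middle 95% of random lists, while ribosomal proteins did not (percentile 99.955). With 4119 sites from each list, 3 ribosome biogenesis genes were bound in Rb-deficient and 0 in control crypt.

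The ribosome biogenesis genes with Myc sites included Ncl, encoding nucleolin, with a score of 90.01 in Rb-deficient and 50.13 in control crypt, and Npm1, encoding nucleophosmin, with 42.38 in Rb-deficient crypt and no promoter site in control crypt. Nop56 (25.47) and Pes1 (30.92) had Rb-deficient sites on an E-box. The Ncl site lay in an intron on chromosome 1, where the 41 bp from 88255387 to 88255427 were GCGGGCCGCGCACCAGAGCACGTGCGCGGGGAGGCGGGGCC. At Pes1, in the 5' UTR on chromosome 11, the bases from 3863962 to 3864002 were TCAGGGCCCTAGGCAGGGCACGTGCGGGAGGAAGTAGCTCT. The best Nop56 site of control crypt (187.31) lay elsewhere, in an intron at 130103801 on chromosome 2. Among ribosomal proteins, Rpl32 scored 113.84 and 63.67, and Rpl10a 98.9 in Rb-deficient crypt without a control promoter site. Bop1 and Ddx21 had no promoter site in either crypt Myc library.

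Over all genes, Myc promoter sites were found at 1841 genes in Rb-deficient crypt and 3829 in control crypt, beside 717 and 3257 after shifts, with 1093 in both. The highest-scored genes of Rb-deficient crypt only were the mitochondrial mt-Nd5, Tbrg4 (85.49), Dazap1 (74.38), 1110008L16Rik and Ppp2r3c (66.87, the same site). Those of control crypt only were Mcee and Mphosph10 (167.92, the same site), Tbk1 (145.17), Actl7a (140.31) and Ttc6 (129.73). At mt-Nd5 the contrast says little, as the control crypt Myc list held 0 mitochondrial sites while every other library held at least 2. Of Rb-deficient crypt Myc sites 89.4% were shared with control crypt, and of control sites 18.8% with Rb-deficient crypt. The 3245 Rb-deficient sites without a control partner had an E-box in 33.7% of cases (32.1% to 35.3%), the shared ones in 3.14% (2.94% to 3.35%). In the other lists, Myc sites of control and Rb-deficient crypt were found at 10 and 4 replication genes, 2 and 2 of nucleotide synthesis, 6 and 4 G1/S regulators, 6 and 3 mitotic genes, 6 and 5 repair genes, 2 and 2 of the Myc network, 1 and 2 of apoptosis, 3 and 4 housekeeping genes and 7 and 2 histones.

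In villi, Myc sites showed little promoter preference, with a promoter share 1.04 times the shifted share in control and 1.24 times in Rb-deficient villus. Promoter sites were found at 164 genes in control villus and 94 in Rb-deficient villus, against 165 and 89.2 after random shifts. No member of the replication, nucleotide synthesis, G1/S, mitotic, Myc network or metabolic target lists had a site in either. Single members of other lists did, such as Ncl (4.83) and Bard1 (4.31) in Rb-deficient villus and the p53 target Bbc3 in both (24.97 and 22.42), as well as 1 histone gene in Rb-deficient and 1 ribosomal protein gene in control villus. The highest-scored genes of Rb-deficient villus only were Gm10801, Ank1 (35.81), 1700030F18Rik (15.84), Msx2 (12.51) and Tpd52l2 (8.94). Those of control villus only were Rnf212 (39.23), Faim3 (23.09), Hydin (17.79), and Mrpl50 and Zfp189 (13.74, the same site). Of Rb-deficient villus Myc sites 71.7% were shared with control villus and 92.9% with Rb-deficient crypt, and of control villus Myc sites 95.1% with control crypt.

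Compared with villi of the same genotype, crypts had Myc at more listed genes in the full lists. In Rb-deficient mice, 13 of 14 ribosome biogenesis genes and all 24 ribosomal protein genes with a crypt Myc site had none in villus, as did 1755 of all 1841 genes with one, so having no villus site was the usual outcome. The highest-scored genes of Rb-deficient crypt only were Ccdc9 (125.43), Gm10655 and Tle3 (121.52, the same site), Rpl32 and Pemt (111.11). In control mice, 162 of the 164 villus genes also had a crypt Myc site, and Ccl17 (2.86), a chemokine gene, was the only gene with a villus site and none within 5 kb in crypt. BC031353, Esco2, a cohesin acetyltransferase gene, Fam102a, Leo1 and Scg5 reached the score cap in control crypt without a control villus site. When Myc sites were joined into 157898 regions, 125949 or 79.8% held control crypt sites alone, 20525 both crypts and 2721 all 4 libraries.

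E2f3 and Myc were found together at many positions that were not promoters, and few of the E2f3 sites there had the E2F motif. Of E2f3 sites, 86.4% in control crypt, 78.0% in Rb-deficient crypt, 85.1% in control villus and 76.2% in Rb-deficient villus lay within 250 bp of a Myc site of any library. Of Myc sites, 22.5%, 67.7%, 94.2% and 95.7% lay near an E2f3 site. E2f3 sites without a Myc site nearby were promoter sites in 53.3%, 65.4%, 66.6% and 64.7% of cases and had the E2F motif in 40.6%, 36.3%, 63.3% and 39.4%. Those near a Myc site had the motif in 1.25%, 1.67%, 2.13% and 2.02%, which is still 2.48, 3.34, 4.03 and 3.86 times the share in their flanks. For sites near a Myc site in the same cells the ratios were lower, 1.90, 2.93, 1.09 and 1.24, and in both villus libraries the interval of the share takes in the share in the flanks. Within the same cells, 18.5% of control crypt Myc, 50.5% of Rb-deficient crypt Myc, 55.7% of control villus Myc and 76.5% of Rb-deficient villus Myc sites were shared with E2f3.

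Of the replication genes with an E2f3 promoter site, 10 of 34 in control crypt and 4 of 37 in Rb-deficient crypt also had a Myc promoter site. These counts lay near those by independence (8.95 and 3.89). None did in villus, where no replication gene had a Myc promoter site. In Rb-deficient crypt, 8 of the 14 ribosome biogenesis genes with Myc also had an E2f3 promoter site (5.38 if independent), as did 6 of the 24 ribosomal protein genes (7.81). The other 6 and 18 had Myc without E2f3, and 4 and 14 of these had no E2f3 site within 5 kb. Both factors had promoter sites at 1233 genes in control crypt (558 if independent), 990 in Rb-deficient crypt (372), 95 in control villus (7.33) and 77 in Rb-deficient villus (11.7). Myc promoter genes in control and Rb-deficient villus were about as many as after random shifts (164 against 165 and 94 against 89.2). Without sites of the other antibody nearby, 5 and 7 remained. In control crypt they numbered 3829 against 3257 and in Rb-deficient crypt 1841 against 717. Without sites of the other antibody nearby, 2844 and 988 remained in these crypt libraries. The villus values therefore do not separate genes bound by both factors from positions found with either antibody. The crypt values do not fully separate them either, as some crypt Myc promoter genes had only sites near an E2f3 site. Mcm3, Mcm4 and Prim1 had E2f3 in all 4 settings and no Myc promoter site in any. In Rb-deficient crypt the highest-scored genes with Myc and no E2f3 site were Rpl32, Pemt (111.11), of phosphatidylcholine synthesis, Rpl10a (98.9), Wipf2 (80.72) and Slc19a1 (78.35), the folate carrier gene. In control crypt they were Actl7a (140.31), Rbm28 (133.5), Gm10916 (119.39), Tmem144 (119.38) and Ttr (118.97). The E2f3 gene had crypt Myc sites in an intron (112.57 in control and 33.32 in Rb-deficient crypt), near but not at its E2f3 site, and the Myc gene had no Myc promoter site in any library. In control villus, E2f3 without Myc was highest-scored at Nasp, a histone chaperone gene, Dclre1a and Nhlrc2 (208.26, the same site), Srsf1 (199.02) and Mcm3. In Rb-deficient villus it was so at Dclre1a, Hist1h2bn, Hist1h3g, Hist2h4 and the repair gene Neil3, all at the cap.

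Few genes of differentiated cells and of other tissues had an E2f3 promoter site, which in control villus is ordinary for lists of this size. None of 20 villus enterocyte genes, 16 immune genes or 14 stromal and endothelial genes had an E2f3 promoter site in any library. Alpi and Anpep, brush border enzymes, are examples. For the enterocyte list the random medians were 3 in control crypt, 4 in Rb-deficient crypt, 1 in control villus and 2 in Rb-deficient villus (percentiles 2.15, 0.435, 19.9 and 3.47), and within 5 kb 5, 4, 1 and 5 members had a site. In control villus the immune, stromal and secretory lists lay at percentiles 24.4, 26.1 and 17.2. In Rb-deficient crypt the same lists lay lower, at 1.27, 1.945 and 0.26. They lay at 3.835, 5.535 and 22.76 in control crypt and at 6.07, 7.555 and 12.555 in Rb-deficient villus. Stem cell and crypt genes had 6 and 4 of 16 members bound by E2f3 in control and Rb-deficient crypt and 0 and 2 in villus, with Axin2 at 38.44, 59.63 and, in Rb-deficient villus, 9.68, while Ascl2 had no site. Intestinal transcription factors had 5, 5, 1 and 3 of 14, with Elf3 in all 4 (87.21, 114.78, 32.8 and 48.5). Secretory genes had 2, 0, 0 and 1 of 23, such as Agr2 (8.26 in control crypt), and genes of other tissues 1, 0, 0 and 1 of 20, each time Mbp (8.4 and 6.76). Control and Rb-deficient crypt Myc sites lay at 2 and 2 enterocyte genes, among them Mttp (38.11 and 70.32), 4 and 3 stem cell genes, 4 and 1 transcription factors, 3 and 1 secretory, 2 and 1 immune, 1 and 0 stromal and 2 and 0 other tissue genes, and the villus Myc lists at none. Of 1113 olfactory receptor genes, 83 had a control crypt Myc site and 13 a Rb-deficient crypt Myc site, in both cases at percentile 0.00. Among genes bound in at least 1 library, the control crypt value lay at percentile 100 (83, random median 41) and the Rb-deficient value at 3.84. All 83 olfactory receptor genes of that pool had a control crypt Myc site, so this percentile of 100 follows from how the pool was made. For E2f3, 2 to 12 olfactory receptor genes per library had a site. In the villus Myc libraries 4 in control and 2 in Rb-deficient villus had a site.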

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

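The tests of a swapped library, of list length, of a common background in control villus Myc and of motif placement were chosen only after the results were seen. The other predictions here were written after the overall motif and promoter shares, but before the values they concern, were known.

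The number of E2f3 sites went opposite ways with genotype in the cell types, while the share of promoter sites (0.82 higher on the log2 scale in Rb-deficient crypt, 0.54 in villus) and the number of promoter genes (0.47 and 1.47 higher) went the same way. The number of E2f3 sites fell by 0.25 on the log2 scale from control to Rb-deficient crypt and was higher by 1 in villus. The share of E2f3 sites with an E2F motif was higher by 0.5 in Rb-deficient crypt and fell by 0.04 in villus, where the intervals overlap. With 1 library on each side, neither difference was tested. Sites were also listed on contigs outside the reference, 145 in Rb-deficient crypt Myc and 201 in control villus Myc, the lowest and highest counts of the 8 libraries, and they were not analysed further here.

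The first pattern is that most Myc sites of 3 libraries lie near an E2f3 site. Shared promoters as the whole cause are argued against, since control villus Myc sites near E2f3 lay at promoters only 1.07 times as often as shifted positions (0.915 to 1.25). A background that carries no motif is also argued against as the source of all such sites in Rb-deficient crypt. Myc sites near E2f3 there had an E-box 2.77 times as often as their flanks. This ratio is a mean over those sites, so it cannot exclude such a background for most of them. For control villus Myc the ratio was 1.14, so that a background common to both antibodies may account for most of that list. Whether such a background comes from open chromatin, repeats or the antibodies stays open, as no input library was used here.

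The second pattern is that the control crypt Myc list, the longest, has little E-box excess. Dilution by weak sites predicted a higher share at its best-scored sites, but these had an E-box only 1.11 times as often as their flanks. This cannot decide on dilution, because a high score need not mark a motif site. In Rb-deficient crypt Myc the E-box share was 4.59% among the better-scored sites and 6.31% among all. A swap with an E2f3 library is argued against, since control crypt Myc sites had the E2F motif 0.879 times as often as their flanks. Placement of events away from the motif as the whole cause is argued against by the ratio within 250 bp, 1.40, which lay below the 2.33 of Rb-deficient crypt Myc. Control crypt E2f3 sites had an E-box ratio of 1.47 there, so the 1.40 need not reflect Myc. A failed or less specific precipitation could fit these values but was not tested, and neither was a true difference between genotypes. The comparison of Myc between crypt genotypes therefore rests on a control list whose sites may not be mostly Myc.

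The third pattern is that E2f3 had promoter sites at more genes, and at mitotic genes in particular, in Rb-deficient villus. List length alone is argued against by a ratio of 1.58 in promoter genes at equal length, and loss of weak sites by the 21 mitotic genes without a control villus site, where score-matched lists had at most 17. Crypt cells within the Rb-deficient villus fraction cannot be told apart from the effect of the deletion. Only 0.431% of Rb-deficient crypt Myc sites with an E-box and no E2f3 site nearby were found in Rb-deficient villus. Of Rb-deficient crypt E2f3 sites with an E2F motif and no Myc site nearby, 58.4% were. In control villus the same sites were found in 0.216% and 31.7% of cases. The villus Myc list is short and near background, so it could miss crypt cells. Loss of Rb stays among the open explanations, as do differences in depth and cell purity between the libraries.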

How the results depend on the processing

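Counts are described as stable when they stayed within 1.5 times the reported count. The 12 shared-site counts were stable with sharing distances of 100 and 1000 bp, after merging events within 500 bp and on autosomes and X only, and so were the 8 numbers of sites under the last 2. Restriction to sites without the other antibody nearby, restriction to promoter sites and the 250 bp motif window were chosen after seeing the data. No block on replicates was possible because each group had 1 library. The share of promoter sites was higher in Rb-deficient than control cells in all 4 genotype pairs (0.82 and 0.54 on the log2 scale for E2f3 in crypt and villus, 1.13 and 0.26 for Myc), but no fit over the pairs was planned or made. For Myc in villus the intervals of the shares overlapped, and both shares lay near the shifted share. The control crypt Myc share was 1.21 times the shifted share. No library's depth is known, so none of the differences in list length can be separated from depth.

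Keeping only the better-scored sites of each list, up to the median rank, lowers counts by construction. The numbers of sites became 16333, 13698, 3702 and 7421 for E2f3 (control crypt, Rb-deficient crypt, control villus, Rb-deficient villus, the order used for all groups of 4 values here) and 79590, 15698, 3611 and 2059 for Myc. Promoter genes became 1832, 2496, 568 and 1570 for E2f3 and 2085, 897, 71 and 52 for Myc. Sites shared between Rb-deficient and control became 3021 in villus and 10545 in crypt for E2f3, and 1594 and 14537 for Myc. Villus sites shared with crypt became 3438 in control and 6312 in Rb-deficient mice for E2f3, and 3431 and 1931 for Myc. Myc sites shared with E2f3 became 14979, 8652, 2224 and 1667.

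With the 4119 best sites of each list, promoter genes became 717, 1115, 616 and 1028 for E2f3, and 118, 224 and 82 for Myc in control crypt, Rb-deficient crypt and control villus. Mitotic members bound in control crypt E2f3 became 11, and ribosome biogenesis members 0 in control crypt Myc and 3 in Rb-deficient crypt Myc. With each pair at the length of its shorter list, shared sites became 4158 for control villus Myc in crypt, 2282 for Rb-deficient villus Myc in crypt and 1836 for Rb-deficient villus Myc in E2f3. These alternatives use fewer sites by construction.

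Without sites of the other antibody, shared sites between Rb-deficient and control became 845 in villus and 2905 in crypt for E2f3, and 32 and 7527 for Myc. Villus sites shared with crypt became 854 in control and 2681 in Rb-deficient mice for E2f3, and 267 and 72 for Myc. Promoter genes became 988 for Rb-deficient crypt Myc, 5 for control villus Myc and 7 for Rb-deficient villus Myc, and the other 5 libraries were stable, as were the 12 counts of bound members of the replication and mitotic lists (E2f3) and of ribosome biogenesis (Myc). At promoter sites only, Myc sites shared with E2f3 became 912, 739, 91 and 87. These counts cover fewer sites by construction, and the cause of the loss beyond that was not tested.

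With a promoter window of 5 kb, promoter genes became 5766 and 1698 for E2f3 in control crypt and control villus, and 11795, 4484, 806 and 499 for Myc, while ribosome biogenesis members became 11 in control crypt Myc and 2 in each villus Myc library. In crypt Myc, ribosomal protein genes became 53 in control and 33 in Rb-deficient mice and metabolic targets of Myc 17 and 12, which turns the direction of both. The direction also turned for apoptosis genes (9 in control and 3 in Rb-deficient crypt) and housekeeping genes (12 and 6). With 500 bp, promoter genes became 2066 in control crypt Myc, 68 in control villus Myc and 49 in Rb-deficient villus Myc. A wider window takes in more sites by construction. Of the bound members of the other lists, 68 of 148 counts moved at equal length, 76 with 5 kb and 34 without sites of the other antibody. Drawing random lists only from genes bound in at least 1 library moved 19 of 160 percentiles across the upper limit of the middle 95%, 18 of them downward. Olfactory receptors in control crypt Myc moved from 0.00 to 100. All 83 receptor genes of that pool had a control crypt Myc site, so the 100 follows from the pool.

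Motif shares were called stable when they stayed within their 95% interval. With a window of 25 bp the E2F shares became 6.21%, 8.57% and 10.1% in control crypt, Rb-deficient crypt and Rb-deficient villus, and the E-box shares 0.699%, 5.92%, 0.627% and 0.661%. With 100 bp they became 7.22%, 10.5%, 12.0% and 12.1%, and 3.82%, 8.36%, 3.75% and 4.10%. With 250 bp they became 9.12%, 13.3%, 13.8% and 15.1%, and 7.36%, 12.5%, 7.73% and 8.19%. A window that searches more sequence finds more motifs by construction, but this need not account for the whole rise. At control crypt E2f3 sites the E-box share went from 1.53% with 50 bp to 4.14% with 100 bp. Their flanks went from 1.08% to 2.24%, so the ratio to the flanks rose from 1.41 to 1.85. Among the better-scored sites the E2F shares became 7.44%, 11.6%, 12.5% and 13.6%, and the E-box share of Rb-deficient crypt Myc 4.59%. Without sites of the other antibody the E2F shares became 40.6%, 36.3%, 63.3% and 39.4%, and the E-box shares 13.7% in Rb-deficient crypt, 0.781% in control villus and 3.31% in Rb-deficient villus. The cause was not tested.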

Other observations

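The CHR test at mitotic genes, with its comparison in crypts, was chosen only after the result was seen, and the CHR test at gained promoter sites was written before its value was known.

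Mitotic genes are known to carry CHR elements near their starts, at which the MuvB core of the DREAM and Myb complexes binds, rather than the E2F motif of replication genes. Of the 22 best mitotic promoter sites of E2f3 in Rb-deficient villus, 15 had a CHR element within 50 bp, 68.2% (45.1% to 86.1%), against 1 of 33 replication sites, 3.03% (0.0767% to 15.8%). Nucleotide synthesis genes had 0 of 10, G1/S regulators 2 of 19 and repair genes 2 of 17. With Rb present, in control crypt, 14 of 18 mitotic sites had the element, 77.8% (52.4% to 93.6%), and 2 of 34 replication sites, and in Rb-deficient crypt 20 of 26 mitotic and 2 of 37 replication sites. The element therefore went with E2f3 sites at mitotic promoters in both genotypes, and it does not tell why control villus lacked them. Mitotic promoters without an E2f3 site were not counted, so the values do not show what brings E2f3 to the others.

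CHR elements did not account for the gained promoter sites as a whole. Of 2046 promoter sites in Rb-deficient villus without a control villus site, 9.87% (8.61% to 11.2%) had the element, and of 830 kept sites 6.75% (5.14% to 8.67%). The share was higher at gained sites, with intervals that overlapped narrowly, which does not show the shares to be alike. As only 9.87% of gained sites had the element, it could not explain most of their lower E2F motif share, 29.0% against 59.0%.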
